A study of Homo sapiens with 6 samples.

How the data were processed

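RNA from U2OS cells, a human osteosarcoma line, was labelled with biotin and hybridised to 6 Illumina expression arrays, which hold beads carrying a probe for each transcript. Per the labels, 3 arrays held cells with a control shRNA and 3 held cells with a stable knockdown of TUSC4. TUSC4 is the older symbol of NPRL2 and is kept here because the array's annotation uses it. The 6 arrays lay on 1 BeadChip, at adjacent positions, with each group in neighbouring places, so position on the chip and group cannot be told apart. Nothing in the labels says that the 3 samples of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

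The deposited values of the first kind were the average bead signal of each probe, an intensity on a linear scale with no normalization between arrays, as the column names and the values show. Per the submitters' processing notes BeadStudio was used, with its version and settings not given in the sources used here. The values of the second kind were the authors' processed log2 values of the same arrays. All 6 columns of these had a median of 6.89 and the same distribution, as quantile normalization gives. The lowest Spearman correlation of a column with the signal of its own array, across probes, was 0.999999. How the authors got from the signal to these log2 values, centring and offset included, is not given in the sources used here. The intensity was used for the results and the authors' log2 values as an alternative.

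The signal table held 47231 probes, of which 3270 had no gene symbol, and neither detection p-values nor control probes were used. The background was therefore corrected with limma's normexp method with an offset of 50 on the average signal, followed by quantile normalization between arrays and log2, which was the course fixed in advance for a table without detection p-values. The offset shrinks the fold changes of dim probes. A detection p was estimated as a substitute. On each array the mode of the log2 signal (density bandwidth 0.05) was taken as background, the probes below the mode gave its standard deviation, and the p was the one-sided normal probability. Probes with an estimated p under 0.05 on at least 3 of the 6 arrays were kept, whatever their group, which left 20657 probes. Of these, 881 had no symbol and entered no gene comparison. This substitute was chosen after the tables were read and before any comparison was run. Each of the 15300 remaining genes was represented by its kept probe with the highest mean log2 intensity, and 3571 genes had more than 1 kept probe. No named gene had kept probes that went opposite ways past the threshold.

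Gene symbols are those of the array. Of the array's 31334 symbols, 21069 matched a current symbol or a single older synonym in a RefSeq gene table (assembly GRCh38.p14), as did 12285 of the genes tested. No genome build is named for the array, so that table served only for names and for which genes neighbour each other.

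The groups were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes on all 6 arrays without covariates. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are TUSC4 shRNA over control shRNA on the log2 scale after the offset, with the moderated standard error (SE). Where a gene was above background on no array of a group, its fold is a bound: the bright group's mean log2 value was set against the mean, over the dim group's arrays, of the higher of the gene's own value and the lowest value above background. The 37 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except those said to be added. They were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists with at least 5 measured genes. Members were also adjusted over the list alone. The preset correlation is small, so camera was run again with a correlation estimated from the data, and fry was run as well. Fry tests whether a list's genes move one way on balance and does not compare them with other genes.

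List members were matched through 1 symbol per member, the one with the brightest kept probe among its listed names and the array symbols that share its current symbol. This was the third matching rule tried, settled after the list results of the earlier 2 rules had been seen. The first rule counted some genes in duplicate and the second used second symbols only where no listed name was on the array. The calls of 2 lists, NRF2 targets and fatty acid synthesis, depend on the rule.

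The genes to be named in every case include TUSC4, BRCA1 and HERC2. To these come the 10 with the largest change in each direction among called genes whose groups did not overlap and whose symbol is not a placeholder. From each list come up to 4 called members with the smallest p, or up to 2 where none was called. Groups of 3 give little power for small changes. The procedure was tested on simulated arrays with the real brightness and size of noise, the noise being drawn for each gene independently. There were 15300 genes tested, for the comparison of 3 TUSC4 shRNA with 3 control shRNA arrays. Of 100 genes changed by 0.5 on the log2 scale it called 22, with a median measured size of 0.31. Of 100 changed by 1 it called 63, with a median measured size of 0.66. Among the genes brighter than the median, counted apart after that low recovery was seen, 21 of 45 and 42 of 44 were called. Of the 96 calls, 3 were genes that had not been changed. A list whose genes were shifted was called and no other list was. With independent noise the simulation cannot tell how often correlated genes make the list test call a list falsely. Far fewer genes were called in it than the 4123 in the data, so its recovery and share of false calls need not hold there.

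The alternatives were no background correction, median scaling, no normalization between arrays, the authors' log2 values, no filter, an estimated detection p under 0.01, and signal above background on all 6 arrays. Others were the mean of a gene's probes, every probe on its own, eBayes with trend and robust settings, array weights, the replicate number as a block, and leaving out each array. Normexp with an offset of 50 was also on the list of alternatives and became the setting used. An offset of 16 and the other matching rules were added after seeing the data.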

Results

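Gene expression was measured on 6 arrays of U2OS cells, an osteosarcoma line, to compare a stable knockdown of TUSC4 with a control shRNA, with 3 samples in each group. TUSC4 (NPRL2) is a subunit of GATOR1, a complex that restrains the growth kinase mTORC1 when amino acids are scarce. The study's title concerns TUSC4 and the stability of the BRCA1 protein. Protein was not analysed here, and the arrays bear on transcripts alone. Between 20378 and 21485 probes per array lay above the estimated background, and the number of arrays limits the precision. Correlations of log2 intensity across kept probes were 0.991 to 0.996 within a group and 0.979 to 0.984 between groups.

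TUSC4 itself was lower in all 3 knockdown samples. Its mean signal was 1008 ± 85.6 (SD, n = 3) with the control shRNA and 398 ± 73.5 (SD, n = 3) with the TUSC4 shRNA. After normalization its log2 fold change was -1.18 ± 0.10 (SE, limma adjusted p = 9.16e-07). This leaves 44.1% of the control intensity with the offset included, which is not the share of transcript left. With an offset of 16, chosen after seeing the data, the log2 fold change was -1.26. The 50 measured genes nearest to TUSC4 on its chromosome, a comparison chosen after seeing the data, had a median log2 fold change of -0.11, with 12 lower and 1 higher past the threshold.

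BRCA1, a homologous recombination gene, had a log2 fold change of -0.42 ± 0.11 (SE, adjusted p = 0.00779) by its brightest probe. Its other kept probes gave -0.19 and 0.05, with limma adjusted p of 0.215 and 0.835 when every probe was tested. The BRCA1 call was lost with the mean of its probes (-0.19, limma adjusted p = 0.202) and without control replicate 1 (-0.33, limma adjusted p = 0.0580), and over the alternatives its adjusted p ranged from 0.00253 to 0.202. Its fall was larger with median scaling (-0.66, limma adjusted p = 0.00253) and without normalization (-0.70, limma adjusted p = 0.00274). HERC2, a ubiquitin ligase, was higher by 0.33 ± 0.10 (limma adjusted p = 0.0207). Median scaling between arrays ended the call of HERC2 (0.09, limma adjusted p = 0.643), as did no normalization (0.05, limma adjusted p = 0.829). HERC2 also missed the threshold without control replicate 2 (0.29), control replicate 3 (0.31), TUSC4 replicate 1 (0.31) or TUSC4 replicate 2 (0.30). Over the alternatives the limma adjusted p of HERC2 ranged from 0.0125 to 0.829. CHEK1, the kinase that halts the cycle when replication stalls, was lower by a larger amount, with a log2 fold change of -1.22 ± 0.10 (limma adjusted p = 6.89e-07). CHEK1 lay in one of the chromosomal segments whose genes shifted together, described below. How much of its fall goes with that segment was not tested.

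**Figure D1:**
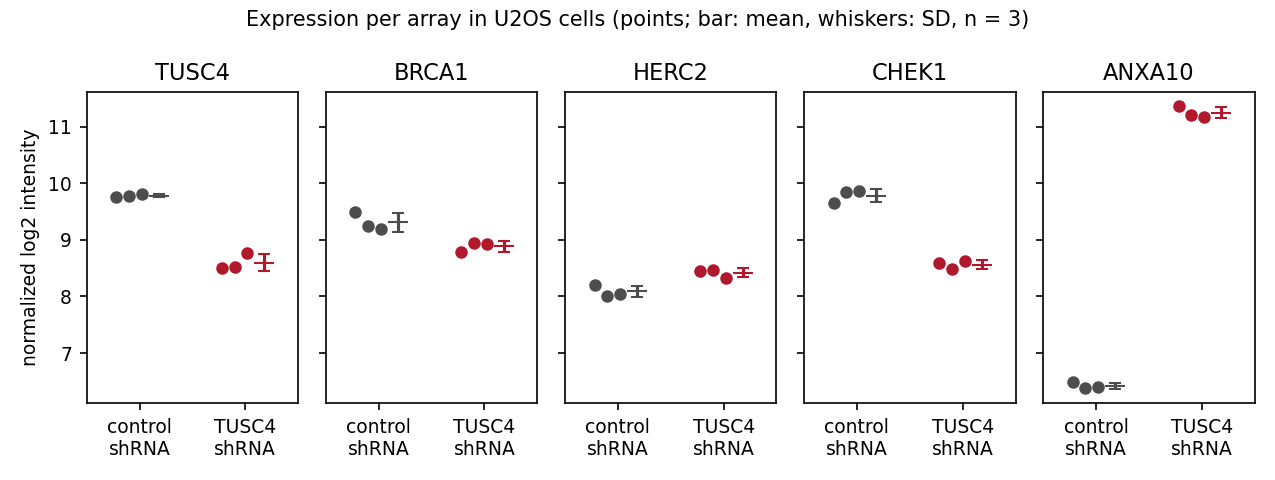
Normalized log2 intensity (vertical axis) of TUSC4, BRCA1, HERC2, CHEK1 and ANXA10 in each of the 3 control shRNA (grey) and 3 TUSC4 shRNA (red) arrays, with group means and SDs beside the points. TUSC4 falls from a mean of 9.78 to 8.59, and ANXA10 rises from 6.42 to 11.25.

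Across the 15300 genes tested, 4123 (26.9%) differed between the groups, 2035 of them higher and 2088 lower in the knockdown. Most changes were small, with a median size of 0.45 on the log2 scale, and 159 genes changed at least 2-fold, of which 48 were higher and 111 lower. The values of the groups did not overlap for 40.5% of genes, against 10% by chance. The balance of directions depended on the scaling. Median scaling gave 620 higher and 3457 lower genes, and no normalization gave 385 and 3516. Those scalings moved the median of all genes by -0.12 and -0.16, and directions below are relative to the typical gene, as quantile normalization sets it. The count of genes changed at least 2-fold was 99 without background correction, 94 with the authors' values, 251 with median scaling, 293 without normalization and 303 with an offset of 16, chosen after seeing the data. Of the 154 genes named by rule, the log2 fold change moved by over 1.5 times for 39 with median scaling, 53 without normalization, 18 with the authors' values and 15 with the mean of a gene's probes.

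The gene with the largest rise was ANXA10, an annexin, at 28.3-fold (log2 4.83 ± 0.10, limma adjusted p = 1.99e-14). Folds of genes with 1 dim group depend on the background correction and offset, and over the alternatives the log2 value of ANXA10 ranged from 4.07 to 5.54. FBXL13, an F-box gene, rose 6.81-fold. KYNU, which encodes the tryptophan-degrading enzyme kynureninase, rose at least 3.95-fold by its brightest probe, with the background correction and offset used. Its control level was not above background by that probe, and its other kept probe gave a log2 fold change of 1.00. SERPINA3, a secreted protease inhibitor, rose 3.72-fold and was above background on 1 of the 3 control arrays. SCARNA18 rose 3.34-fold, MMP3, a secreted metalloproteinase, 3.16-fold, C5orf46 3.06-fold and DDIT4, an inhibitor of mTORC1 signalling induced by stress, 2.87-fold. SPANXA1 and SPANXE, cancer-testis genes, rose 4.54-fold and 3.28-fold. Their near-identical copies can share probes, so the copy that changed is uncertain. Over the alternatives the log2 fold change ranged from 2.13 to 3.30 for FBXL13, 1.52 to 3.27 for KYNU, 1.25 to 2.55 for SERPINA3, 1.66 to 2.61 for SPANXA1, 1.31 to 2.03 for SPANXE and 1.16 to 2.10 for MMP3, the lowest in each case with the authors' values.

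Among the genes that fell, the chemokine CXCL14 had the largest change with the settings used, a log2 fold change of -2.39 ± 0.11 (limma adjusted p = 2.20e-09). PSG4, of the near-identical pregnancy-specific glycoproteins, had a log2 fold change of -2.23, and TNNC1, troponin C of slow muscle and heart, -2.06. CTAG2, a cancer-testis gene with near-identical copies, fell at least 2.98-fold, with the background correction and offset used, to a level not above background. The matrix and secreted protein genes MFAP5, FSTL1 and LUM fell, with log2 fold changes of -1.88, -1.79 and -1.75. IL2RB was at -1.66, BEX1, of a near-identical family, at -1.65 and FAM65B (RIPOR2) at -1.58. The other kept probe gave -0.74 for BEX1 and -1.05 for LUM. IL2RB was above background on 1 of the 3 knockdown arrays and FAM65B on 2. The mean of its probes gave -1.09 for PSG4 and -1.24 for CTAG2. Over the alternatives the log2 fold change ranged from -2.84 to -1.21 for CTAG2, -2.30 to -1.06 for IL2RB, -2.12 to -1.05 for FAM65B, -2.89 to -1.80 for CXCL14, -2.62 to -1.45 for TNNC1 and -2.36 to -1.33 for MFAP5, the smallest falls being those with the authors' values.

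Most genes of the ATF4 and amino acid response rose. Of 40 measured members, 28 rose, 2 fell and 10 did not pass, with 30 rising and 3 falling when adjusted over the list alone. DDIT4 rose by 1.52 ± 0.11, the asparagine synthetase gene ASNS by 1.40 ± 0.11 and the serine synthesis gene PSPH by 1.15 ± 0.12. TRIB3, a pseudokinase gene that ATF4 induces, rose by 0.97 ± 0.10. The list's median log2 fold change was 0.46, and camera gave an adjusted p of 4.01e-11. With an estimated correlation its adjusted p = 0.240. No list passed with an estimated correlation: limma's camera then gave a lowest adjusted p of 0.112, 5 lists with an unadjusted p under 0.05 and 0 after adjustment. Fry called 17 lists, 8 of the 9 that camera called at the preset correlation among them, all but fatty acid synthesis. The others were homologous recombination, non-homologous end joining, mTORC1, glycolysis and hypoxia, NF-kB, osteoblast, TGF-beta, interferon and epithelial genes.

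Genes of cholesterol synthesis and its control fell. Of 24 measured members, 16 fell, 1 rose and 7 did not pass, with the same counts of 16 and 1 when adjusted over the list alone. INSIG1, a sterol-sensing regulator, had a log2 fold change of -1.40 ± 0.11 and the squalene epoxidase gene SQLE -1.03 ± 0.10. FDFT1, which encodes squalene synthase, had -0.78 ± 0.09. The median was -0.54 with a camera adjusted p of 1.70e-07, and the adjusted p = 0.112 with an estimated correlation. For fatty acid synthesis 6 of 16 members fell and 1 rose (7 and 1 adjusted over the list alone). SCD, a desaturase gene, had -1.03 ± 0.13 and FADS1, another, -0.81 ± 0.10. The list's median was -0.21 with a camera adjusted p of 0.0478, close to the threshold, and its adjusted p = 0.672 with an estimated correlation. This call was lost without control replicate 1 (0.135), control replicate 3 (0.0605), TUSC4 replicate 2 (0.0511) or TUSC4 replicate 3 (0.0792). It was also lost with members matched by their first listed symbol (camera adjusted p = 0.0538), and the adjusted p ranged from 0.00154 to 0.135 over the 19 alternative fits.

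Among p53 target genes 15 of 29 measured members rose and 1 fell (20 and 1 adjusted over the list alone). GADD45A, a stress-response gene, rose by 1.11 ± 0.10, the DNA repair gene XPC by 0.73 ± 0.11 and the kinase gene PLK2 by 0.65 ± 0.10. TP53I3, an oxidoreductase gene, fell by 0.54 ± 0.10, with -0.35 for the mean of its probes. The median was 0.30 with a camera adjusted p of 3.22e-05, and the adjusted p = 0.112 with an estimated correlation. The median was 0.13 with median scaling and 0.09 without normalization.

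Genes of G2/M and mitosis fell, 12 of 39 members in both adjustments, with none higher past the threshold. The transcription factor gene FOXM1 had a log2 fold change of -0.93 ± 0.09 and the cytokinesis genes ANLN and PRC1 had -1.10 ± 0.12 and -0.74 ± 0.12. AURKB, a mitotic kinase, had -0.64 ± 0.10. The median was -0.18, with a camera adjusted p of 0.000681 and an adjusted p = 0.260 with an estimated correlation. Median scaling gave a median of -0.38. E2F targets and DNA replication genes did not pass as a list (4 higher and 5 lower of 41, camera adjusted p = 0.995), or 3 and 5 adjusted over the list alone. TK1 was lower at -0.64 and PRIM1 at -0.52.

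Of 16 replication-dependent histone genes 8 rose and 2 fell, or 11 and 2 adjusted over the list alone. HIST2H2AA3 rose by 0.94 ± 0.10, HIST2H2AC by 0.91 ± 0.09 and HIST1H2BG by 0.79 ± 0.09. Histone probes can match several near-identical genes, and 7 of the 14 members with a chromosomal position lay in chromosomal segments whose genes shifted together. Relative to each member's 50 nearest measured neighbours, a comparison chosen after seeing the data, the median was 0.23. The median was 0.35 with a camera adjusted p of 0.000414, and the adjusted p = 0.240 with an estimated correlation. In the unfolded protein response list 9 of 21 members fell and none rose, in both adjustments. CREB3L2, a transcription factor gene, had -1.13 ± 0.11, the chaperone partner SDF2L1 -0.68 ± 0.10 and EDEM1, which aids disposal of misfolded proteins, -0.65 ± 0.13. The median was -0.25 with a camera adjusted p of 0.0147, and the adjusted p = 0.270 with an estimated correlation. Relative to neighbouring genes this median was -0.16.

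In the NRF2 target list 8 of 15 members rose and 1 fell, or 9 and 4 adjusted over the list alone. OKL38 (OSGIN1) rose by 1.18 ± 0.11 and NQO1, a quinone reductase gene, by 0.79 ± 0.11, while GCLC, which encodes the catalytic part of the enzyme that starts glutathione synthesis, fell by 0.68 ± 0.10, with -0.43 for the mean of its probes. The median was 0.31, with a camera adjusted p of 0.0462 and an adjusted p = 0.260 with an estimated correlation. Median scaling lowered the median to 0.07 and ended the call (camera adjusted p = 0.0534). Without control replicate 3 the camera adjusted p was 0.0605, without TUSC4 replicate 1 it was 0.0543, and with members matched by their first listed symbol it was 0.0972. Over the 19 alternative fits it ranged from 0.00438 to 0.0729, matching rules aside. Without normalization the medians of all lists lay lower, at 0.30 for the ATF4 list, 0.22 for histones, -0.38 for the unfolded protein response, -0.46 for fatty acid synthesis and -0.63 for fibroblast markers, with all genes at -0.16.

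**Figure D2:**
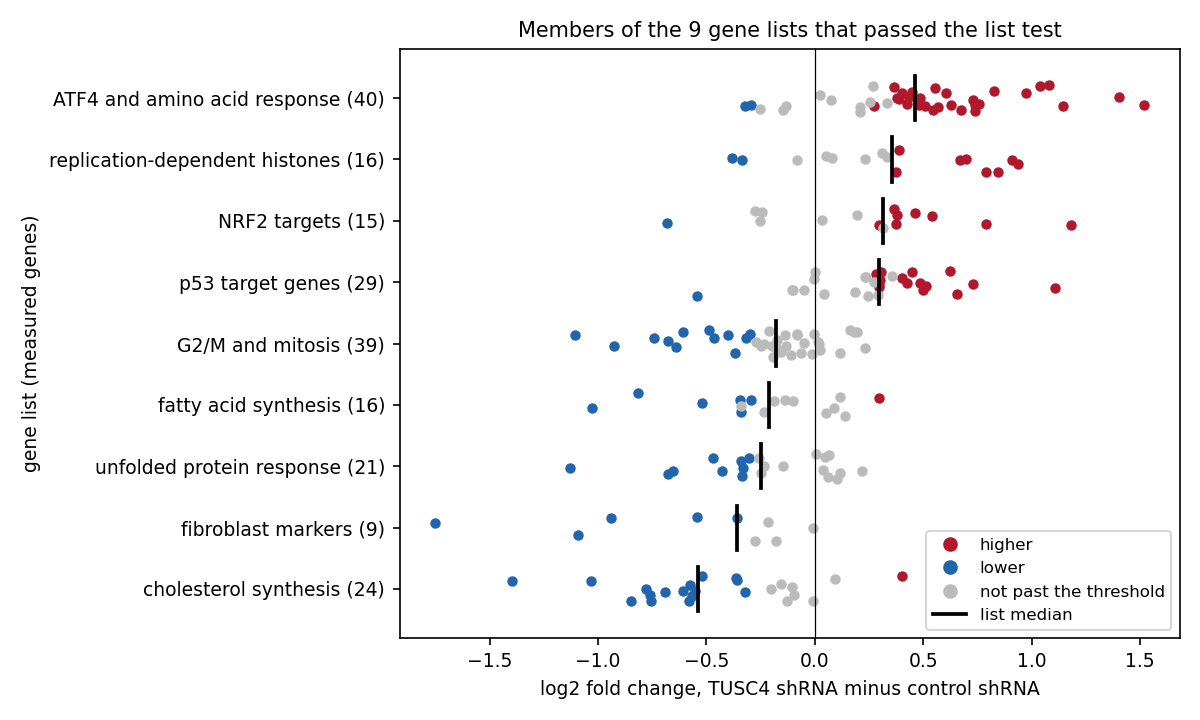
Log2 fold change of each measured member (points, horizontal axis) of the 9 gene lists called by camera at its preset correlation, with the number of measured genes after each name and the list median as a black bar. Red and blue points passed an adjusted p of 0.05 and grey points did not. The medians run from -0.54 for cholesterol synthesis to 0.46 for the ATF4 list.

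The other 28 lists did not pass camera with the settings used. Homologous recombination had 11 genes higher and 1 lower of 39 (13 and 1 adjusted over the list alone), the lower one being BRCA1. The list had a camera adjusted p of 0.0618. Over the alternatives this ranged from 0.00628 to 0.341, and the list's median of 0.07 became -0.11 with median scaling. It passed camera with the authors' values (0.0338), without background correction (0.0413), without the filter (0.00628), without control replicate 3 (0.0498) and without TUSC4 replicate 3 (0.0483), and it passed fry (adjusted p = 0.00726). The Fanconi anaemia pathway had 2 higher of 14 (camera adjusted p = 0.480; 0 adjusted over the list alone) and non-homologous end joining 2 higher of 10 (0.146; 1 alone), with DCLRE1C higher by 0.64, a call lost without normalization (0.36). DNA damage checkpoint signalling had 2 higher and 1 lower of 19 (0.995; 2 and 1 alone). The lower gene was CHEK1, which lay in a chromosomal segment whose genes shifted together. Mismatch and base excision repair had 3 higher and 4 lower of 24 (0.971; 3 and 4 alone), with MUTYH higher by 0.73 and NEIL2 lower at -0.55. The other kept probes of MUTYH both gave 0.05, and the mean of its probes gave 0.28 (limma adjusted p = 0.0488).

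The lists of TUSC4's partners did not pass camera with the settings used. Of 12 genes of the GATOR complexes, 2 were higher and 2 lower (camera adjusted p = 0.971; 2 and 2 adjusted over the list alone), the lower ones being TUSC4 and SEH1L (-0.69 ± 0.12). The higher ones were WDR59 (0.45 ± 0.11) and C16orf35 (NPRL3, the partner of TUSC4 in GATOR1, 0.36 ± 0.13), and both calls were lost with median scaling (0.21 and 0.14) and without normalization (0.17 and 0.10). The C16orf35 call was lost in 8 of the 19 alternative fits, those without control replicate 2 (0.32), control replicate 3 (0.31), TUSC4 replicate 1 (0.33) or TUSC4 replicate 2 (0.25) among them. Among 30 genes of mTORC1 and its lysosomal regulators 7 were higher and 1 lower (0.146; 7 and 1 alone). They included DDIT4 and the autophagy kinase gene ULK1 (0.68 ± 0.10). The list's median of 0.06 became -0.09 with median scaling. It passed camera without the filter (adjusted p = 0.0493) and passed fry (adjusted p = 0.00216). In the list of chromosomal neighbours of TUSC4, 4 of 15 genes were lower and none higher (0.105; 4 and 0 alone), HYAL3 at -0.66 and SEMA3B at -0.62. This list passed without TUSC4 replicate 2 (camera adjusted p = 0.0483). Lysosome and autophagy genes had 6 higher and 4 lower of 42 (0.480; 6 and 4 alone), with the proton pump gene ATP6V1A lower at -0.80. Cytosolic ribosomal proteins had 3 and 2 of 47 (0.971; 1 and 0 alone), and ribosome biogenesis and MYC targets 3 and 2 of 30 (0.843; 3 and 2 alone), with NOP56 higher by 0.83 and CDK4 lower at -0.72.

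In the glycolysis and hypoxia list 13 of 33 genes were higher and 6 lower (camera adjusted p = 0.0705; 13 and 7 adjusted over the list alone), with ANKRD37 higher by 0.88 and PFKFB4 by 0.77. It passed camera without the filter (0.00628), with the mean of a gene's probes (0.0476, median 0.23 against 0.10) and without TUSC4 replicate 3 (0.0331). Pentose phosphate and nucleotide synthesis had 2 higher and 5 lower of 21 (0.512; 2 and 5 alone), PRPS1 at -1.01. Mitochondrial respiratory chain genes had 0 higher and 4 lower of 41 (0.361; 0 and 2 alone), NDUFA9 at -0.46. The proteasome list had 1 higher and 4 lower of 30 (0.998; 1 and 4 alone), and PSMA2 was lower at -1.43. Heat shock proteins had 3 higher and 5 lower of 14 (0.379; 3 and 5 alone). CRYAB, a small heat shock protein gene, was lower at -1.43 and HSPA1A, which has a near-identical copy, higher by 0.65.

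Fibroblast markers, fixed as genes that cells of another type would bring, fell. Of 9 measured members 5 were lower and none higher (6 and 0 adjusted over the list alone), with LUM at -1.75 ± 0.12, COL3A1 at -1.09 ± 0.12 and PDGFRB at -0.94 ± 0.10. The median was -0.36 with a camera adjusted p of 0.000114, and the adjusted p = 0.129 with an estimated correlation. The matrix list, which shares LUM, COL3A1, POSTN and COL6A3 with it, had 6 higher and 13 lower of 34 (0.0717; 8 and 16 alone), among them TNC higher by 1.02 and COL5A2 lower at -1.22. It passed camera without the filter (0.00396), with genes above background on all 6 arrays (0.0479) and without control replicate 2 (0.0207). Epithelial markers had 3 lower of 6 (0.0618; 3 and 0 alone), KRT17 at -1.18 and KRT8 at -0.69. They passed camera with median scaling (0.0161), without normalization (0.0144) and without control replicate 1 (0.0427) or TUSC4 replicate 2 (0.0474). Haematopoietic markers had 1 higher and 1 lower of 8 (0.843; 1 and 1 alone), CD68 at 0.55, a call lost without normalization (0.29), and CD34 at -0.69, or -0.35 by the mean of its probes. Neural and embryonic kidney line markers had 1 and 2 of 7 (0.565; 1 and 2 alone), with NES lower at -0.98.

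Signalling and lineage lists did not pass camera with the settings used. Osteoblast and bone genes had 1 higher and 4 lower of 13 (camera adjusted p = 0.103; 1 and 5 adjusted over the list alone), with BMP4 lower at -1.02 and SPP1, osteopontin, higher by 0.98. They passed camera without the filter (0.0262). TGF-beta targets had 2 higher and 6 lower of 19 (0.247; 2 and 6 alone), with TAGLN at -1.22 and LTBP2 at -0.83. Regulators and markers of the epithelial-mesenchymal transition had 2 and 2 of 9 (0.631; 2 and 3 alone), CDH11 being lower at -1.44. Interferon-stimulated genes had 6 higher and 7 lower of 37 (0.951; 6 and 7 alone), with HERC5 at -1.44 and IFITM2 at -0.76. NF-kB targets and cytokines had 5 higher and 2 lower of 16 (0.0972; 5 and 2 alone), with CCL2 higher by 0.56 beside MMP3, and passed camera without normalization (0.0471). Immediate early genes had 3 and 3 of 17 (0.480; 5 and 3 alone), with SPRY2 lower at -0.51. Wnt and Notch targets had 1 higher and 3 lower of 11 (0.933; 2 and 3 alone), CCND1 being higher by 0.64 and AXIN2 lower at -0.49. Median and mean differed in sign for the GATOR, proteasome, interferon, haematopoietic and mismatch repair lists, all with a median within 0.06 of 0.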

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

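The tests of chromosomal segments were chosen only after the neighbour result was seen. The others were set down before the result each measures.

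Kept probes without a gene symbol entered no comparison of genes, and 101 of these 881 probes passed the threshold when all kept probes were tested together, 47 higher and 54 lower. Testing all kept probes together was chosen after a first, lower count from a fit of these probes alone had been seen.

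Only 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real split gave 4123 changed genes, 159 of them at least 2-fold. By limma the highest of the other splits gave 0 of each, with 113 to 467 genes under an unadjusted p of 0.05 against 5761. Each of those splits put arrays of both groups on each side, so the group difference added to their spread. Their low counts therefore cannot show what arrays without a group difference would give. Each real count was reached by 1 split, the real one. For gene lists the real split gave 9 and the highest other split 7, at the preset correlation.

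Opposite shifts of the ATF4 list (median 0.46) and the cholesterol synthesis list (median -0.54) were set against 3 technical explanations. The central 95% of the medians of 10000 random lists of like brightness ended at 0.11 above for the first and at -0.13 below for the second, so brightness alone did not give them. Without normalization the lists still stood 0.45 above and -0.61 below the median of all genes. Relative to each member's 50 nearest measured neighbours the ATF4 median was 0.51, over the 37 of 40 members with a position. The cholesterol median shrank to -0.44 and that of the unfolded protein response list (-0.25) to -0.16. For histones it was 0.23 over the 14 members with a position, against 0.35 over all 16. A response to the loss of TUSC4 is one biological hypothesis, and a difference between 2 separately grown lines, or in their nutrient supply, stays untested.

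Neighbouring genes changed together. Across 12078 genes with a position, test statistics of adjacent genes correlated at 0.18, and the highest of 1000 shuffled orders gave 0.03; genes are not independent replicates. The correlation was 0.15 without pairs from one gene family and 0.17 relative to genes of like brightness, both above all shuffled orders. Genes 10 places apart still correlated at 0.12, which is consistent with long segments that differ in copy number between the cells, though shared regulation of broad domains remains open. The median of its 50 nearest measured neighbours, -0.11 (12 lower, 1 higher), does not account for the -1.18 of TUSC4. Such a median cannot show a shorter segment. In the list of chromosomal neighbours of TUSC4, 4 of 15 genes were lower and none higher, the lowest at -0.66.

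Fibroblast markers fell (5 of 9), and fewer fibroblast-like cells in the knockdown samples cannot be told apart from lower expression in the U2OS cells. Of COL1A1, COL1A2, COL3A1 and DCN, abundant in fibroblasts, 2 met the prediction, which called for at least 3 if such cells were the source and at most 1 if not. COL1A1 was at -0.96 and COL3A1 at -1.09. DCN was above background on 0 of the 3 control arrays and COL1A2 on 1, which counts against such cells unless those probes respond poorly. U2OS cells themselves express matrix genes.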

How the results depend on the processing

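The offset of 16 and the other matching rules were chosen after seeing the data. TUSC4 was lower past the threshold in all 19 alternative fits (log2 -1.46 to -1.07). The count of changed genes ran from 3033 to 4521, within 1.5 times 4123. Median scaling gave 620 higher, 3457 lower and 251 changed at least 2-fold, and no normalization gave 385, 3516 and 293. The median of all genes was then -0.12 and -0.16. Median scaling centred each array on the median of all 47231 probes, and only 43.1% to 45.5% of probes per array were above background. It therefore aligned probes at background level and not the expressed ones, so these 2 settings are not separate checks. Why the expressed probes differed between arrays was not tested. Genes changed at least 2-fold numbered 99 without background correction, 94 with the authors' values and 303 with an offset of 16, since less offset shrinks dim probes less; for the other settings the cause was not tested. Called lists numbered 14 without the filter, 0 with an estimated correlation and 17 by fry, and the cause was not tested. The estimated correlation was below the preset 0.01 for cholesterol synthesis (-0.034), p53 targets (9.68e-05), fibroblast markers (-0.055) and NRF2 targets (-0.025). A larger correlation therefore does not account for the loss of those calls. For the other called lists it was above 0.01, up to 0.29 for fatty acid synthesis. Called lists numbered 7, 9 and 7 with the first listed symbol, every symbol, or own names first.

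Leaving out 1 array gave 3033 to 4079 changed genes, 1479 to 2048 higher, 1554 to 2031 lower, 159 to 179 changed at least 2-fold and 8 to 10 lists. The 9 called lists passed in all 19 fits except NRF2 targets (13) and fatty acid synthesis (12). Of 154 named genes 107 kept the call in each alternative that measured them and 47 lost it in at least 1 (145 were measured in all 19, and 9 in 18), most often without normalization (31) or with median scaling (27); none changed sign. Medians of 20 uncalled lists changed sign in some setting. Same-numbered samples of the groups did not deviate together (r of 0.0746, 0.0764 and -0.0934). This gave no sign of pairing by number, but so few arrays cannot exclude that such samples were handled together. With the number as a replicate block 4077 genes changed (2020 higher, 2057 lower, 159 at least 2-fold) and 9 lists were called. Dim genes limit the count: the simulated recovery was lower for them.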

Other observations

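The segments and cancer-testis families below were chosen after their values were seen. Windows of 51 neighbouring measured genes were compared with 200 shuffled orders, whose window medians ran from -0.24 to 0.20. Observed window medians ran from -0.45 to 0.31. Overlapping windows beyond the shuffled range were joined into 17 segments, 10 higher and 7 lower. The median of a whole segment can lie within that range, as from CDK14 to GIGYF1 on chromosome 7 (0.17). On chromosome 13, 60 of the 104 genes from HTR2A to CHAMP1 were lower and 6 higher. On chromosome 7, 51 of 110 from GPNMB to EGFR were lower and 7 higher. In the other direction, 37 of 80 genes from DEFB127 to POLR3F on chromosome 20 were higher and 2 lower, as were 35 and 1 of 82 from LINC00115 to DFFA on chromosome 1. The segments held 1210 of the 12078 genes with a position and 554 of the 3500 changed ones.

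Most changed genes with a position thus lay outside these segments. Genes 10 places apart outside them still correlated at 0.08. A candidate explanation is that the control and knockdown cells grew from cells with different gains and losses of chromosome parts, which U2OS cells carry in variable form. The correlation of 0.12 at 10 places fits that, but DNA was not analysed here.

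Some families of cancer-testis genes, which most adult tissues keep silent, held several changed members, and no enrichment was tested. Of 8 measured SPANX genes 6 were higher and 1 lower. Of 20 GAGE genes 19 were lower, as were 3 of 3 CT45A genes, 3 of 4 PAGE genes, 2 of 3 CTAG genes and 3 of 11 MAGEA genes. Family medians were 0.53 for SPANX, -1.14 for GAGE and -0.10 for MAGEA, and 0.30, -1.31 and -0.29 with median scaling. The copies within SPANX, GAGE and CT45A are nearly identical and can share probes, so these counts are not of independent genes.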
